A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

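Gene expression was measured by RNA sequencing, and the labels give total RNA from budding yeast of the W303 background as the input. Cells lacking GRR1, the gene for an F-box protein of an SCF ubiquitin ligase, and wild-type (WT) cells were grown at 30 °C in synthetic complete medium with 2% glucose to an OD600 of 0.2, and tunicamycin was added at 1 µg/ml. Tunicamycin blocks the first step of N-linked glycosylation and loads the endoplasmic reticulum (ER) with misfolded protein. RNA was taken at 0 h and at 4 h, per the labels' protocols, in 2 biological replicates of each of the 4 groups, 8 libraries in all. The lysates were prepared in a buffer for ribosome profiling and sequenced on an MGI instrument. Ribosome profiling and translation efficiency were not analysed here. Untreated cultures sampled at 4 h were not analysed here, so time in culture and tunicamycin move together in every comparison of 4 h with 0 h.

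The submitters' processing notes name cutadapt 2.6, Bowtie2 2.3.5, STAR 2.7.3a, DESeq2 and build R64, without their roles or order. The deposited files hold raw read counts per gene, split into all exon positions, 5′ UTR, coding region and 3′ UTR, and made with the counting program of plastid per the file headers. That program gave each read of 25 to 100 nt to a single position 25 nt from its 5′ end, per the file headers. The same files hold RPKM values that the authors' program scaled by countable length and by all counted reads, including those outside genes. Countable length in bases is a further deposited column, and it was used here only to check the RPKM values. Separate deposited tables hold log2 fold changes with standard errors, made by the authors for 4 h against 0 h in each genotype. Those tables also give the authors' p-values, raw and adjusted, and they were used only for comparison with the fit made here. How the counting treated strand is not given in the sources used here. YAL004W, which lies antisense within SSA1, held 24 reads over the 8 libraries against 223439 for SSA1. Reads that map to several places are not described either, so near-identical paralogs and overlapping genes are uncertain.

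Each file lists 6696 gene regions, of which 105 have a countable length of 0. A RefSeq symbol of the R64 assembly was found for 6008 identifiers, and 182 more took their names from the authors' tables. Coordinates are those of the R64 RefSeq annotation. Reads counted in genes numbered 12119744 and 12083581 in WT at 0 h, and 8360928 and 8871653 in WT at 4 h. In grr1-deficient cells they numbered 8256539 and 4885844 at 0 h, and 8155337 and 12380049 at 4 h. A count of 0 allows up to 3 reads in a library, which came to between 0.242 and 0.614 CPM (counts scaled to library size). Such floors and counting intervals cover counting error only, because the reads carry no molecular identifiers. The replicates differed by more than sampling noise in all 4 groups, with chi-square per degree of freedom of 19.77, 6.17, 168.9 and 469.9 in the order above, so every library was kept as a separate replicate.

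Exon counts were tested with edgeR 4.0.16 in R 4.3.3. All 8 libraries entered 1 quasi-likelihood fit with robust estimation, a coefficient per group, TMM scaling and the default expression filter, which kept 5855 genes. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The 5 comparisons were tunicamycin at 4 h against 0 h in WT and in grr1-deficient cells, the difference of those 2 responses as an interaction, and grr1-deficient against WT at 0 h and at 4 h. Fold changes are log2 with standard errors (SE), and edgeR added a prior count of 0.125 to them. CPM values are TMM scaled and given as mean ± SD of 2 libraries unless stated. A gene with 10 reads or fewer in a group is given as a ratio with its exact 95% counting interval, and a gene with 0 reads as a lower bound against 3 reads over the group.

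In all, 39 gene lists holding 808 names were fixed, of which 806 names were found. They cover UPR signalling, the SCF ligase and Ubp3, ER chaperones and oxidative folding, ER-associated degradation (ERAD), N-glycosylation, UDP-GlcNAc synthesis, ER translocation, COPII and COPI traffic, phospholipid and inositol synthesis, ergosterol synthesis, cell wall integrity, calcineurin targets, the general stress response, cytosolic and mitochondrial chaperones, ribosomal proteins and ribosome biogenesis. Metabolic lists cover amino acid synthesis under Gcn4, sulfur amino acids, amino acid permeases of the SPS pathway, hexose transport and glucose sensing, glucose-repressed carbon metabolism, glycolysis, the respiratory chain and TCA cycle, the mitochondrial genome, the iron regulon and the phosphate response. The others are the proteasome, autophagy, oxidative stress under Yap1, drug efflux under Pdr1, G1/S genes, G2/M genes, histones, pheromone response, MATa-specific genes, MATalpha-specific genes, meiosis and sporulation, and the auxotrophic marker loci, which served as a label check. The other 38 lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 38. Results of 1 of these lists are not reported here, though it is included in the adjustment and in the counts of lists that passed. Counts adjusted over the list alone used the p-values of the members only. No list had a member at 0 reads in a whole group among the genes tested.

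Genes named in the text are the 8 largest rises and falls in each response and the 6 largest in the other comparisons, among genes past the threshold with a mean of at least 20 reads and groups that do not overlap. Up to 4 members of each list with the smallest p are named too, and GRR1, UBP3, BRE5, HAC1, IRE1, KAR2, PDI1 and ERO1 are named throughout. The groups, lists, naming rule, tests and most alternatives were chosen before the data were examined. Alternatives covered DESeq2 size factors, total counts, no filter or a mean of at least 50 reads, DESeq2 1.42.0 and limma voom, a replicate block, a fold threshold of 2, leaving out ribosomal protein genes or each library, fry, and an estimated correlation in camera. Those added after seeing the data were leaving out both replicate 2 libraries of the grr1-deficient strain, leaving out the mitochondrial genome, coding-region counts, voom with a weight per library, and DESeq2 beside the authors' tables.

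The fit was tested on counts simulated from the means, depths and spread of these libraries. In the WT response, 62.6% of genes changed 2-fold and 88.9% of those changed 4-fold were called, with 18 false calls among 5612 unchanged genes. The grr1-deficient response gave 66.7% and 88.0% (13 among 5609), and the interaction 24.0% and 76.5% (8 among 5619). Genotype comparisons gave 64.6% and 89.0% at 0 h and 62.6% and 88.0% at 4 h. Camera called 0 of 38 lists in each, but the inputs held no correlation between genes. They changed at most 100 genes per fold, so they do not bound false calls in the more variable grr1-deficient libraries.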

Results

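Gene expression was measured by RNA sequencing in 8 libraries of W303 budding yeast, 2 biological replicates in each of 4 groups. WT and grr1-deficient cells were sampled at 0 h and after 4 h of tunicamycin, a drug that blocks N-linked glycosylation and so places the ER under folding stress. Depth ranged from 4885844 to 12380049 gene reads per library, and between 6159 and 6337 genes had reads. The series asks how the transcriptome responds to ER stress in cells with and without Grr1, a ubiquitin ligase subunit that its title links to turnover of the deubiquitinase Ubp3 and to translation of HAC1 mRNA.

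GRR1 itself (YJR090C, R64 chromosome X, 590872 to 594327) had 1179 and 1384 reads in the WT libraries at 0 h, and 1794 and 1829 reads in those at 4 h. The grr1-deficient libraries held 2 and 3 reads at 0 h, and 6 and 12 reads at 4 h, in replicate order. Of these, 1 read lay in the coding region. GRR1 measured 140.0 ± 12.6 CPM (mean ± SD, n = 2) in WT at 0 h against 0.413 ± 0.209 CPM in grr1-deficient cells. At 4 h the means were 166 ± 1.78 and 0.819 ± 0.178 CPM. Without TMM scaling, STE2, the receptor of MATa cells, lay between 60.5 and 409.6 CPM in the 8 libraries, and MF(ALPHA)1, a pheromone gene of MATalpha cells, at 2.26 CPM or less. All marker loci were read in every library, and on the same unscaled CPM LEU2 lay between 122.1 and 232.9, URA3 between 27.6 and 99.7, HIS3 between 17.0 and 34.6, ADE2 between 25.9 and 46.8, and TRP1 between 9.24 and 20.6.

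Replicate 2 of the grr1-deficient strain stood apart from replicate 1 at both times. Transcripts of 19 open reading frames of the mitochondrial genome summed to 889316 and 1094623 reads in replicate 1 at 0 h and 4 h. Replicate 2 held 158 and 19 such reads. In CPM without TMM scaling, this sum was 107700 and 134200 in grr1-deficient replicate 1, 32.34 and 1.535 in replicate 2, 18470 and 17240 in the WT libraries at 0 h and 46290 and 50300 in those at 4 h. The mitochondrial reading frame Q0092 went the other way, with 144 and 258 reads in replicate 1 against 18668 and 94706 in replicate 2. Among 5614 nuclear genes, 11 differed by more than 4-fold between these replicates at both times. HXT13, a hexitol and hexose transporter gene, was higher in replicate 2 by 4.64 and 5.81 log2 at 0 h and 4 h. MLS1, encoding malate synthase of the glyoxylate cycle, fell by 6.06 and 2.91 there, and the succinate-fumarate carrier gene SFC1 by 4.72 and 2.14. The SD between replicates of nuclear genes was 0.278 and 0.204 log2 in WT at 0 h and 4 h, against 0.586 and 0.484 in grr1-deficient cells.

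**Figure D1:**
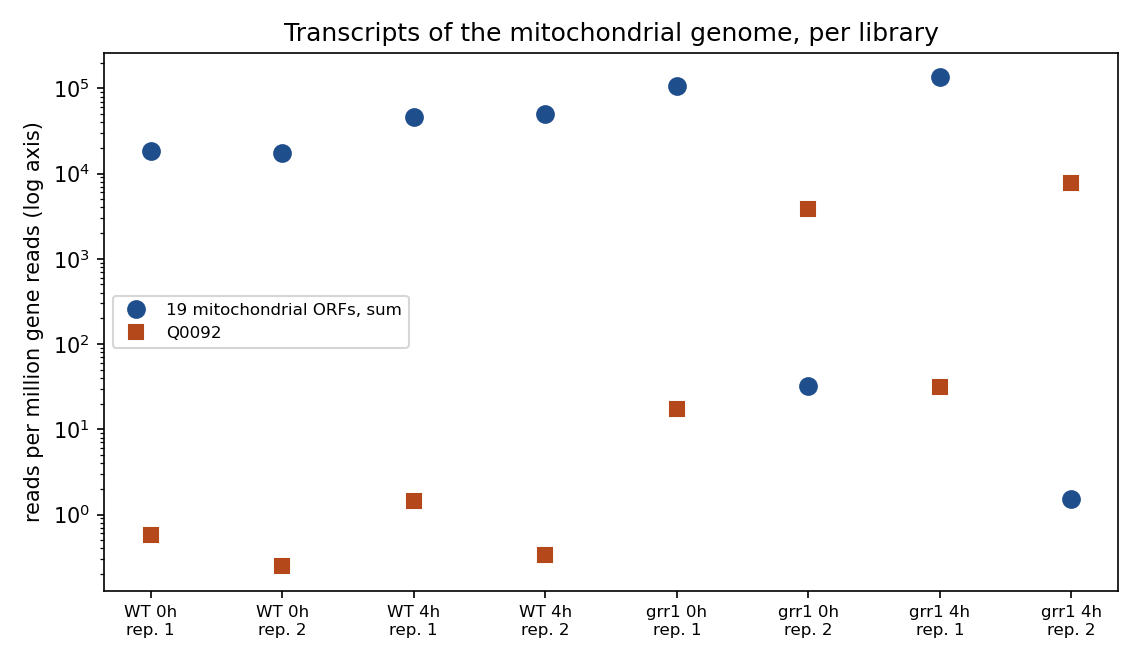
Reads relative to all gene reads in each of the 8 libraries, on a log axis, for the sum of 19 mitochondrial open reading frames and for Q0092. Replicate 2 of the grr1-deficient strain had 158 and 19 reads in the sum at 0 h and 4 h, against 889316 and 1094623 in replicate 1, while Q0092 was higher in replicate 2.

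The first comparison asked what changed in WT cells between 0 h and 4 h of tunicamycin. Transcripts for ER folding, ER-associated degradation, cell wall repair and general stress defence rose, and those for making ribosomes and histones fell, as did Gcn4-regulated and phosphate response genes. These are calls of the camera test at a preset correlation, and with an estimated correlation each list had an adjusted p = 0.296 or more, while total counts ended the calls of ERAD (0.0518) and cell wall integrity (0.0920). KAR2 (YJL034W, chromosome X, 381327 to 383375), the ER Hsp70 chaperone, rose from 1031 ± 68.2 to 4660 ± 463.8 CPM (mean ± SD, n = 2). ERO1 (YML130C, chromosome XIII, 11483 to 13174), the ER thiol oxidase, rose from 95.1 ± 3.74 to 863.5 ± 91.9 CPM. PDI1 (YCL043C, chromosome III, 48653 to 50221), protein disulfide isomerase, rose from 514.9 ± 52.8 to 1216 ± 173 CPM. Their log2 changes were 2.18 ± 0.19, 3.18 ± 0.26 and 1.24 ± 0.18 (± SE), with edgeR adjusted p of 1.6e-05, 1.1e-05 and 0.000408. HAC1 (YFL031W, chromosome VI, 75179 to 76147), whose spliced mRNA encodes the transcription factor of the unfolded protein response (UPR), was at 1163 ± 50.4 and 1293 ± 94.0 CPM. Its log2 change of 0.15 ± 0.19 did not pass the edgeR test (adjusted p = 0.512), and the counts do not separate its spliced and unspliced forms.

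In all, 3841 of 5855 genes passed the edgeR test in WT, 1905 higher and 1936 lower. GRR1 did not pass (log2 0.25 ± 0.13, adjusted p = 0.137), nor did UBP3 (YER151C, chromosome V, 469686 to 472424) at −0.18 ± 0.18 (adjusted p = 0.416). The largest rise was that of ULI1 (YFR026C, chromosome VI, 205748 to 206257), a gene known to be induced by the UPR, from 2.06 to 647 CPM (log2 8.28 ± 0.46, adjusted p = 5.1e-06). Genes for the small heat shock proteins HSP12 and HSP26 rose by 7.10 ± 1.24 and 6.48 ± 1.15, and RTA1 by 6.39 ± 0.39. CPP3 rose by 6.26 ± 1.56. Other large rises started from 10 reads or fewer at 0 h, so they are given as ratios with 95% counting intervals. These were 139.8-fold (64 to 382) for the Rab GTPase gene YPT53, 107.5-fold (36.5 to 524) for YDL114W and 83.2-fold (38.0 to 228) for POT1, encoding the peroxisomal thiolase. The acid phosphatase gene PHO3 fell furthest, from 452 to 2.72 CPM (log2 −7.38 ± 0.31). It was followed by RPL9A (−6.63 ± 0.30), RPS22A (−5.95), RPS9B (−5.66), ASC1 (−5.48), RPS16B (−5.43), RPL12A (−5.37) and RPP2A (−5.34), all genes for proteins of the ribosome.

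**Figure D2:**
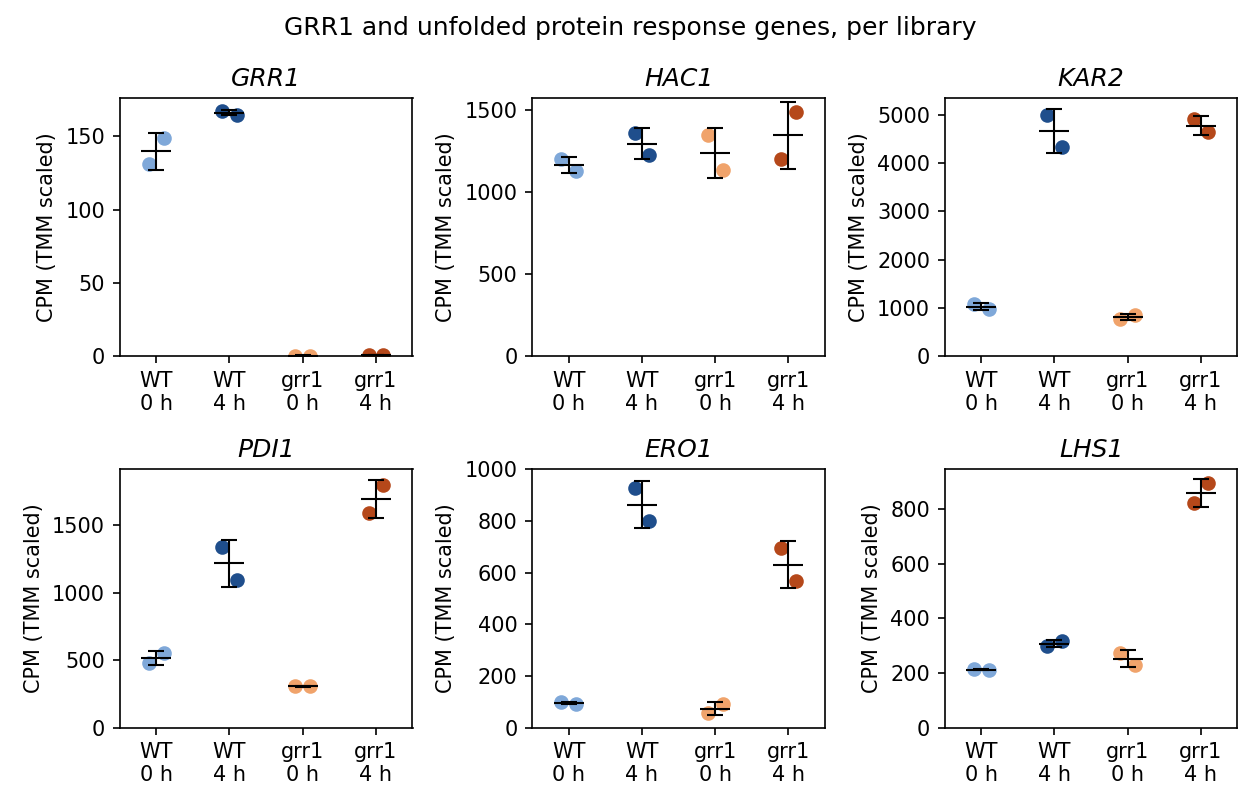
TMM-scaled CPM of GRR1, HAC1, KAR2, PDI1, ERO1 and LHS1 in the 4 groups, with a point per library and the mean ± SD of 2 libraries. KAR2 rose from 1031 to 4660 CPM in WT and from 814.7 to 4767 CPM in grr1-deficient cells, while HAC1 lay between means of 1163 and 1345 CPM.

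Of 38 gene lists, 16 passed the camera test in WT, 8 higher and 8 lower. All 135 ribosomal protein genes fell (median log2 −4.60, camera adjusted p = 1.6e-49), as did all 50 ribosome biogenesis genes (−2.82, adjusted p = 2.7e-34), among them NSR1 at −4.51 and SSF1 at −3.48. Ribosomal protein genes held 24.7% and 23.2% of gene reads in the WT libraries at 0 h and 1.82% and 1.79% at 4 h. Autophagy genes rose, 21 of 22 (median 1.91, adjusted p = 9.5e-10), with ATG39, a receptor for autophagy of the perinuclear ER, at 4.47 ± 0.22. ER chaperone and oxidative folding genes rose, 13 higher and 2 lower of 16 (median 1.21, adjusted p = 0.00386), including the nucleotide exchange factor SIL1 at 2.94 ± 0.14. Calcineurin targets rose, 6 of 9 (2.12, adjusted p = 0.00121), with the protease gene YPS3 at 3.60. Cytosolic and mitochondrial chaperones rose, 15 higher and 2 lower of 22 (0.82, adjusted p = 0.00653), with HSP42 at 4.72. Phosphate response genes fell, 11 lower and 1 higher of 13 (−1.75, adjusted p = 1.5e-05), with PHO5 at −4.86. Histone genes fell, 9 of 10 (−1.31, adjusted p = 0.00274), with HTB2 at −3.49. MATa-specific genes fell, 6 of 7 (−1.99, adjusted p = 0.00365), with STE2 at −3.46. Each list from the ribosomal proteins to the MATa-specific genes had an adjusted p = 0.296 with an estimated correlation.

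General stress genes rose in WT, 22 higher and 1 lower of 25 (median 3.42, camera adjusted p = 1.3e-09, and adjusted p = 0.457 with an estimated correlation), with the glucokinase gene GLK1 at 4.29 ± 0.16. Amino acid synthesis genes under Gcn4 fell, 27 of 31 (−1.72, adjusted p = 6.1e-06, and adjusted p = 0.595 with an estimated correlation), with ARG3 at −4.01 and LEU9 at −4.92. G2/M genes fell, 10 of 14 (−0.96, adjusted p = 0.00592, 0.422 with an estimated correlation, median −0.21 with total counts), with CLB2 at −2.04. ERAD genes rose, 10 higher and 2 lower of 17 (0.83, adjusted p = 0.0404), and glucose-repressed genes rose, 11 higher and 2 lower of 23 (2.07, adjusted p = 0.00615). Both had an adjusted p = 0.489 with an estimated correlation. DER1 and DFM1, which act in retrotranslocation of ER proteins, rose by 2.75 and 2.21, and FOX2 and CAT2, of fatty acid oxidation, by 2.43 and 2.64. Cell wall integrity genes rose, 11 higher and 2 lower of 18 (1.05, adjusted p = 0.0179, and adjusted p = 0.590 with an estimated correlation), with YPS1 at 2.91. Adjusted over the list alone, the counts were equal to those above except for general stress (24 higher, 1 lower) and ERAD (10 higher, 3 lower).

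The other 22 lists did not pass in WT. Meiosis and sporulation genes had 11 of 14 members higher (adjusted p = 0.0518), sulfur amino acid genes 13 lower and 2 higher of 22 (0.0548), SPS permeases 7 lower and 1 higher of 11 (0.0627), ergosterol synthesis 14 lower and 1 higher of 23 (0.110), and oxidative stress under Yap1 9 higher and 3 lower of 18 (0.127), each in the camera test. The proteasome had 14 members higher of 32 (0.178), the respiratory chain and TCA cycle 5 higher and 1 lower of 37 (0.190), drug efflux 6 higher and 5 lower of 11 (0.201) and G1/S genes 3 higher and 10 lower of 20 (0.284). UPR signalling had 1 member higher and 4 lower of 6 (0.385), COPII and COPI traffic 14 higher and 5 lower of 27 (0.434) and N-glycosylation 8 higher and 13 lower of 28 (0.594). Adjusted over the list alone, counts (higher, lower) were proteasome (7, 0), respiratory list (2, 0), G1/S (5, 10) and N-glycosylation (9, 13). The remaining 10 lists had adjusted p of 0.683 or more: ER translocation (4 higher, 4 lower), UDP-GlcNAc synthesis (2, 1), MATalpha-specific genes (1, 0), pheromone response (5, 6), phospholipid synthesis (5, 7), hexose transport (3, 5), iron (5, 5), SCF ligase and Ubp3 (2, 2), glycolysis (4, 11) and the mitochondrial genome (0, 0), with equal counts adjusted over the list alone. For the MATalpha, pheromone, phospholipid, hexose, iron and SCF lists the median, mean and test differed in sign. The grr1-deficient replicates widen the shared spread of mitochondrial genes, so 0 calls do not show an unchanged WT level (median 0.72).

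Relative scaling sets the direction of weakly changed genes. Scaling by total counts in place of TMM moved the median gene from 0.03 to 0.78 log2 in WT, and the split became 3340 higher and 957 lower. It ended the calls of cell wall integrity (adjusted p = 0.0920), ERAD (0.0518) and glucose-repressed genes (0.0812), and the sulfur amino acid list (0.0357), SPS permeases (0.0437) and the proteasome (0.0341) passed. With a replicate block the sulfur list (0.0405), SPS permeases (0.0334) and the respiratory list (0.0122) passed. The sulfur list also passed without WT 0 h replicate 2 (0.0262) or grr1-deficient 0 h replicate 1 (0.0381) or 2 (0.0391), SPS permeases without any 1 of the grr1-deficient libraries (at most 0.0391), and the respiratory list without grr1-deficient 0 h replicate 1 (0.0407). Meiosis genes passed as higher without WT 0 h replicate 1 (0.0246) or 2 (0.0445) or grr1-deficient 0 h replicate 1 (0.0205) or 2 (0.0271), within 0.00907 to 0.183, and ergosterol synthesis as lower without grr1-deficient 0 h replicate 1 (0.0426, within 0.00130 to 0.155). Adjusted p ranged from 0.00604 to 0.0986 for the sulfur list over its alternatives, 0.00650 to 0.0849 for SPS permeases, 0.0184 to 0.306 for the proteasome and 0.00284 to 0.544 for the respiratory list. ERAD also missed the threshold without WT 4 h replicate 1 (0.0632) or WT 0 h replicate 2 (0.0556), and with a replicate block (0.0534). Over 12 alternatives other than the estimated correlation, adjusted p ranged from 0.00254 to 0.0920 for cell wall integrity, from 0.00121 to 0.0632 for ERAD, from 0.000670 to 0.0812 for glucose-repressed genes and up to 0.0437 for the other 13 lists. IRE1, the ER stress sensor (−0.45 ± 0.14, adjusted p = 0.0205), and BRE5, the Ubp3 cofactor gene (−1.03 ± 0.14, adjusted p = 0.000247), were lower in WT at 4 h in edgeR. Total counts turned UBP3 from −0.18 to 0.56 in WT with an edgeR call (adjusted p = 0.0115, within 0.0115 to 0.718 over its alternatives). They ended the BRE5 call (−0.29, 0.129, within 2.5e-10 to 0.129) and turned IRE1 to 0.30, and IRE1 also missed the threshold without WT 4 h replicate 1 (0.0814), WT 0 h replicate 2 (0.129) or WT 4 h replicate 2 (0.105), within 0.000250 to 0.129 over its alternatives. CPP3 missed it without WT 0 h replicate 1 (0.101) or 2 (0.105), WT 4 h replicate 1 (0.0597) or 2 (0.0602) and grr1-deficient 4 h replicate 2 (0.0503), within 7.4e-20 to 0.177.

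In grr1-deficient cells, the same 4 h of tunicamycin went with rises in the ER folding, ER degradation and vesicle traffic genes and with smaller falls of the ribosome genes. With an estimated correlation the list calls ended, at an adjusted p = 0.184 for ER folding and 0.405 for the other lists named. KAR2 rose from 814.7 ± 54.0 to 4767 ± 194 CPM (mean ± SD, n = 2), PDI1 from 306.2 ± 2.36 to 1692 ± 143 CPM and ERO1 from 73.5 ± 26.5 to 631 ± 90.1 CPM. Their log2 changes were 2.55 ± 0.19, 2.47 ± 0.19 and 3.10 ± 0.26 (± SE), with edgeR adjusted p of 0.000105, 0.000111 and 0.000132. HAC1 was at 1238 ± 152 and 1345 ± 203 CPM, and its log2 change of 0.12 ± 0.19 did not pass (adjusted p = 0.639). UBP3 (0.46 ± 0.19, adjusted p = 0.0733), IRE1 (0.13, 0.482) and BRE5 (−0.37, 0.0621) did not pass either. GRR1 remained at 0.413 and 0.819 CPM.

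Altogether 2696 of 5855 genes passed the edgeR test in grr1-deficient cells, 1259 higher and 1437 lower. ULI1 again had the largest rise, from 2.79 to 336 CPM (log2 6.90 ± 0.44, adjusted p = 0.000123). MNC1 rose by 3.90 ± 0.27, YET2, a relative of the ER membrane protein BAP31, by 3.63 ± 0.14 and YOL037C by 3.51 ± 0.58. From 10 reads or fewer at 0 h, YJR079W rose 46.2-fold (12.6 to 385, 95% counting interval), YDL114W 15.9-fold (8.51 to 33.5) and the seripauperin genes PAU12 and PAU11 11.1-fold (4.60 to 35.1) and 10.5-fold (3.39 to 52.4). Falls were led by AIM33 (−3.28 ± 0.81), YDR133C (−3.25 ± 0.21), the endonuclease gene HO (−3.10 ± 0.44), the respiratory growth gene RGI2 (−2.94 ± 0.44) and AIM20 (−2.74 ± 0.18). The near-identical hexose transporter genes HXT7 and HXT6 fell by 2.73 and 2.71, and the uracil phosphoribosyltransferase gene FUR1 fell from 229 to 35.1 CPM. Reads may not separate HXT6 from HXT7, nor YDR133C and YOL037C from genes that overlap them.

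The camera test passed 13 of 38 lists in grr1-deficient cells, 7 higher and 6 lower. ER chaperone and oxidative folding genes rose, 12 higher and 1 lower of 16 (median log2 1.71, adjusted p = 6.2e-10), with SIL1 at 2.94 ± 0.14 and JEM1 at 2.04 ± 0.12. Calcineurin targets rose, 6 of 9 (1.47, adjusted p = 5.1e-05), with YPS3 at 2.23. Both had an adjusted p = 0.184 with an estimated correlation. Ribosomal protein genes fell, 135 of 135 (−1.60, adjusted p = 1.6e-25), and ribosome biogenesis genes, 48 of 50 (−1.07, adjusted p = 1.1e-16), with NSR1 at −2.13. Histone genes fell, 8 of 10 (−0.96, adjusted p = 5.9e-05), and G2/M genes, 9 of 14 (−0.87, adjusted p = 0.000169), with HTA2 at −2.27 and CLB2 at −1.64. Autophagy genes rose, 16 of 22 (0.83, adjusted p = 2.1e-06), with ATG17 at 2.49. COPII and COPI traffic genes rose, 17 higher and 3 lower of 27 (0.78, adjusted p = 0.00125), with the coat gene SEC24 at 1.42, and ERAD genes rose, 9 of 17 (0.59, adjusted p = 0.00125), with DER1 at 1.96. Each of the lists from the ribosomal proteins to ERAD had an adjusted p = 0.405 with an estimated correlation.

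Cell wall integrity genes rose in grr1-deficient cells, 11 higher and 1 lower of 18 (median 0.83, camera adjusted p = 0.00207, and adjusted p = 0.470 with an estimated correlation), with NCW2 at 2.21. Gcn4-regulated amino acid genes fell, 22 of 31 (−0.81, adjusted p = 0.000195, and adjusted p = 0.753 with an estimated correlation), with LEU9 at −1.98. General stress genes rose, 8 higher and 2 lower of 25 (0.64, adjusted p = 0.0231, and adjusted p = 0.820 with an estimated correlation), with TSL1, of trehalose synthesis, at 1.60 and list medians of 1.10 with replicate 1 and 0.47 with replicate 2. Of the 25 lists that did not pass, N-glycosylation had 9 members higher and 2 lower of 28 (adjusted p = 0.193), with the dolichol kinase gene SEC59 at 1.16. The respiratory list had 1 higher and 6 lower of 37 (0.100), with medians of −1.07 with replicate 1 and −0.34 with replicate 2. Glucose-repressed genes had 1 higher and 6 lower of 23 (0.218), and their median turned from −1.14 with replicate 1 to 0.07 with replicate 2. Adjusted over the list alone, counts differed for ribosome biogenesis (49 lower), histones (9 lower), calcineurin targets (7 higher), COPII and COPI traffic (18 higher, 3 lower), N-glycosylation (9 higher, 1 lower), the respiratory list (1 higher, 5 lower) and glucose-repressed genes (1 higher, 5 lower). For drug efflux, glycolysis and the mitochondrial genome the median, mean and test differed in sign.

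Total counts moved the median gene from 0.04 to 0.10 log2 here and gave 1218 genes higher and 1216 lower. The general stress call ended with fry (adjusted p = 0.152), without grr1-deficient 0 h replicate 1 (0.365) and without grr1-deficient 4 h replicate 2 (0.218), within a range of 4.3e-06 to 0.365 over 12 alternatives, against 0.0315 at most for the other 12 lists. The respiratory list passed as lower with a replicate block (adjusted p = 0.000133), with total counts (0.0251), and without grr1-deficient 0 h replicate 2 (2.7e-07) or 4 h replicate 1 (0.00675), within 3.2e-10 to 0.661. Glucose-repressed genes passed as lower without grr1-deficient 0 h replicate 2 (0.000730, within 2.8e-08 to 0.898). Leaving out that library also passed drug efflux (0.0451, within 0.00776 to 0.362), G1/S genes (0.0311, within 0.00524 to 0.175), iron (0.0451, within 0.0451 to 0.661) and meiosis genes (0.0155, within 0.0155 to 0.359). The AIM33 call ended without grr1-deficient 4 h replicate 1 (0.0845) or 4 h replicate 2 (0.143), within 8.4e-12 to 0.143 over its alternatives. That of PAU11 ended without WT 4 h replicate 1 (0.0536) or 2 (0.0538), without grr1-deficient 0 h replicate 1 (0.198) or 2 (0.0880), and without grr1-deficient 4 h replicate 1 (0.129), within 2.9e-05 to 0.198.

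The interaction asked which genes responded differently in the grr1-deficient cells. The ER chaperone gene KAR2 and the ER oxidase gene ERO1 gave no called difference over all 8 libraries. Ribosomal protein and ribosome biogenesis genes fell less in grr1-deficient cells and general stress genes rose less. Phosphate response and MATa-specific genes had a higher response there, and glucose-repressed genes a lower one. None of these 6 list calls held with an estimated correlation (adjusted p = 0.227 for the phosphate response, 0.514 for general stress and 0.381 for the others). KAR2 differed by 0.37 ± 0.26 log2 (grr1-deficient minus WT response, ± SE, edgeR adjusted p = 0.291), ERO1 by −0.08 ± 0.34 (0.879), HAC1 by −0.03 ± 0.28 (0.939), UBP3 by 0.64 ± 0.26 (0.0885) and IRE1 by 0.57 ± 0.20 (0.0506). Without both replicate 2 libraries of the grr1-deficient strain, ERO1 turned to 0.49, in a fit whose spread came from the WT libraries alone. PDI1 rose more in grr1-deficient cells, by 1.23 ± 0.26 (adjusted p = 0.00717), as did the ER Hsp70 gene LHS1, by 1.24 ± 0.20 (0.00209). GRR1 itself differed by 0.84 ± 0.46 (0.314), from counts near the floor in grr1-deficient cells. In all, 2182 genes passed, 1166 with a higher and 1016 with a lower response in grr1-deficient cells.

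The largest positive differences were those of genes that fell in WT: PHO3 at 5.38 ± 0.43 (edgeR adjusted p = 0.000133), PHO5 at 4.38 ± 0.22, HMS2 at 4.36 ± 0.60, YJR146W at 4.22 ± 0.90, RPL9A at 4.11 ± 0.35 and the hexose transporter gene HXT4 at 3.99 ± 0.72. PHO5 fell from 377 to 13.0 CPM in WT and was at 23.1 and 16.6 CPM in grr1-deficient cells. The largest negative differences were those of HSP12 (−6.95 ± 1.48), TMA10 (−6.65 ± 0.37), POT1 (−5.63 ± 0.74), HSP26 (−5.23 ± 1.40), the decarboxylase gene ARO10 (−5.01 ± 0.84) and YMR206W (−4.98 ± 0.58). TMA10 rose from 10.8 to 574 CPM in WT but was already at 971 CPM at 0 h in grr1-deficient cells, and at 511 CPM at 4 h.

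**Figure D3:**
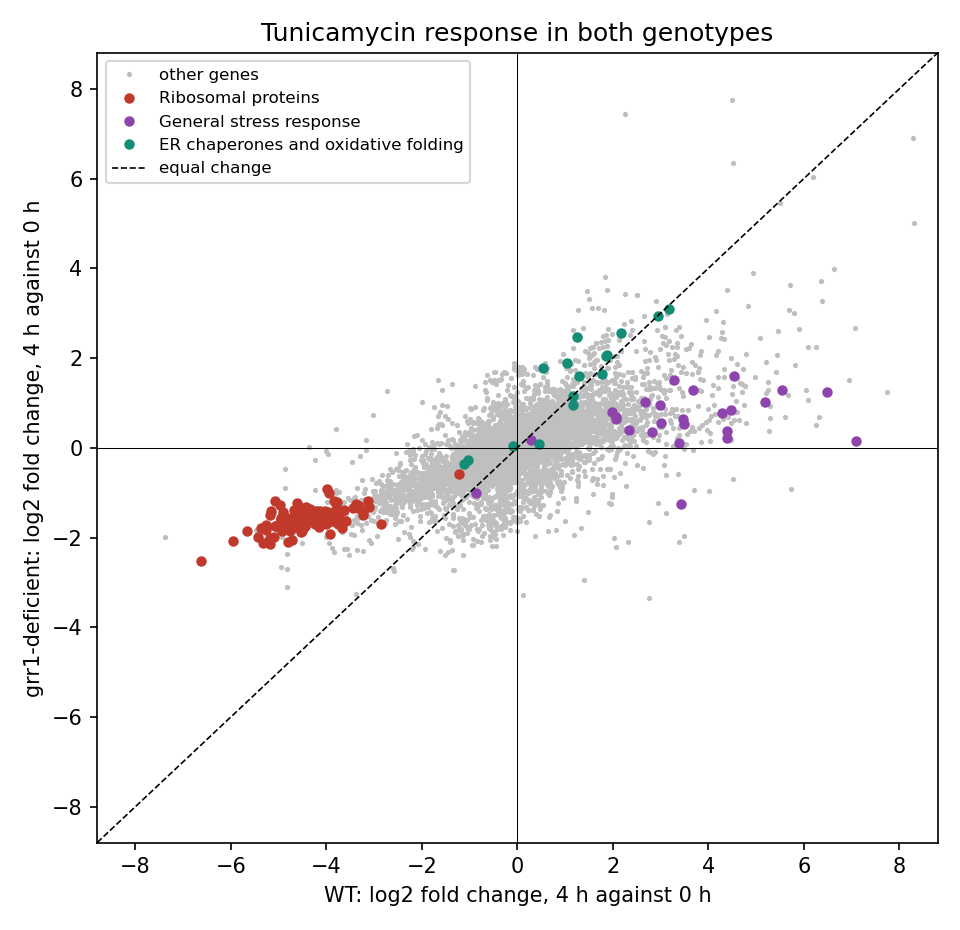
Log2 fold change at 4 h against 0 h of tunicamycin in WT (x axis) and in grr1-deficient cells (y axis), with a point for each of 5855 genes and a dashed line of equal change. Ribosomal protein genes (red) had medians of −4.60 and −1.60, general stress genes (purple) 3.42 and 0.64, and ER chaperone genes (green) 1.21 and 1.71.

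Ribosomal protein genes fell less in grr1-deficient cells, with 134 of 135 past the test of the difference (median 3.02, camera adjusted p = 7.3e-53), led by RPL6A at 3.88 ± 0.20. The ribosome biogenesis list followed with 49 of 50 (1.77, adjusted p = 3.0e-28), with DBP2 at 3.13. MATa-specific genes had a higher response, 4 of 7 (2.17, adjusted p = 0.000260), with STE2 at 3.14. Glucose-repressed genes had a lower response, 11 of 23 (−3.01, adjusted p = 2.1e-07), with CAT2 at −3.09 ± 0.29. These 4 lists had an adjusted p = 0.381 with an estimated correlation. Phosphate response genes had a higher response, 11 of 13 (1.66, adjusted p = 2.4e-07, and adjusted p = 0.227 with an estimated correlation), with PHO11 at 3.84. General stress genes rose less, 20 of 25 (−2.83, adjusted p = 2.1e-12), with PGM2 at −4.18 and GLK1 at −3.50, and autophagy genes rose less, 14 of 22 (−1.05, adjusted p = 4.4e-06), with ATG39 at −4.28. Both had an adjusted p = 0.514 with an estimated correlation.

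Gcn4-regulated amino acid genes fell less, 18 of 31 (median 1.10, camera adjusted p = 0.000480), with LEU9 at 2.94 and CPA1 at 1.51, and N-glycosylation genes had a higher response, 11 higher and 2 lower of 28 (0.48, adjusted p = 0.0366), though their median turned to −0.21 with total counts. Both had an adjusted p = 0.708 with an estimated correlation. Cytosolic and mitochondrial chaperones had a lower response, 10 of 22 (−0.68, adjusted p = 0.00528, and adjusted p = 0.403 with an estimated correlation), with HSP42 at −2.97 and HSP78 at −2.37. Respiratory and TCA genes had a lower response, 6 of 37 (−1.45, adjusted p = 0.000260, and adjusted p = 0.747 with an estimated correlation), with the isocitrate dehydrogenase gene IDH1 at −2.18. ER chaperone genes (5 higher of 16, median 0.19, adjusted p = 0.316) and UPR signalling genes (3 higher of 6, 0.67, adjusted p = 0.145) did not pass as lists. Adjusted over the list alone, counts differed for ribosome biogenesis (50 higher), general stress (21 lower), autophagy (15 lower), MATa (5 higher), Gcn4 (19 higher, 1 lower), chaperones (11 lower), N-glycosylation (14 higher, 2 lower) and UPR signalling (4 higher). For G1/S genes the median, mean and test differed in sign.

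The 2 grr1-deficient replicates did not give equal values for several of these lists. Against the same WT libraries, the glucose-repressed median of the difference was −3.49 with replicate 1 and −1.99 with replicate 2, and that of ribosomal proteins 2.80 and 3.19. A fit without both replicate 2 libraries of the grr1-deficient strain takes its spread from WT alone, so its count of calls is not comparable. Total counts turned the split to 451 higher and 2486 lower, moved the median gene from 0.03 to −0.65 and ended the call of PDI1 (0.53, adjusted p = 0.127, within 1.4e-05 to 0.127 over its alternatives), which also ended without WT 4 h replicate 2 (0.0501). The number of called genes was 1365 without WT 0 h replicate 2, 1397 without WT 4 h replicate 1 and 1272 without WT 4 h replicate 2.

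N-glycosylation lost its call with total counts (adjusted p = 0.262), with a replicate block (0.0919), and without WT 0 h replicate 1 (0.0816), WT 4 h replicate 2 (0.0875), grr1-deficient 4 h replicate 1 (0.131) or grr1-deficient 0 h replicate 2 (0.0821) or both grr1-deficient replicate 2 libraries (0.0794), within 0.00830 to 0.262 over 12 alternatives. The Gcn4 list missed the threshold with fry (0.0538, the highest of its 12), and the respiratory list with fry (0.195, the highest of its 12) and without grr1-deficient 0 h replicate 1 (0.0565), against 0.0385 at most for the other 8 lists reported. Sulfur amino acid genes (adjusted p = 0.0551) passed with total counts (0.0385), without WT 0 h replicate 2 (0.0217), WT 4 h replicate 1 (0.0498) or grr1-deficient 4 h replicate 2 (0.0114), and with a replicate block, within 0.00619 to 0.242, and pheromone response genes (0.158) with total counts (0.0385, within 0.0272 to 0.557). SPS permeases (0.112) passed without grr1-deficient 4 h replicate 1 (0.0146, within 0.0146 to 0.267). HSP12 and HSP26 kept their calls without grr1-deficient 0 h replicate 1 or 2 and lost them without any other library. For HSP12 the adjusted p was then 0.0625 and 0.0742 without WT 0 h replicates 1 and 2, 0.0532 and 0.0649 without those of WT 4 h, and 0.0800 and 0.0674 without those of grr1-deficient cells at 4 h. For HSP26 it was 0.128, 0.147, 0.106, 0.117, 0.126 and 0.136 in the same order, and 0.0564 with a replicate block. Over all alternatives the ranges were 1.6e-10 to 0.0800 and 3.9e-07 to 0.147.

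**Figure D4:**
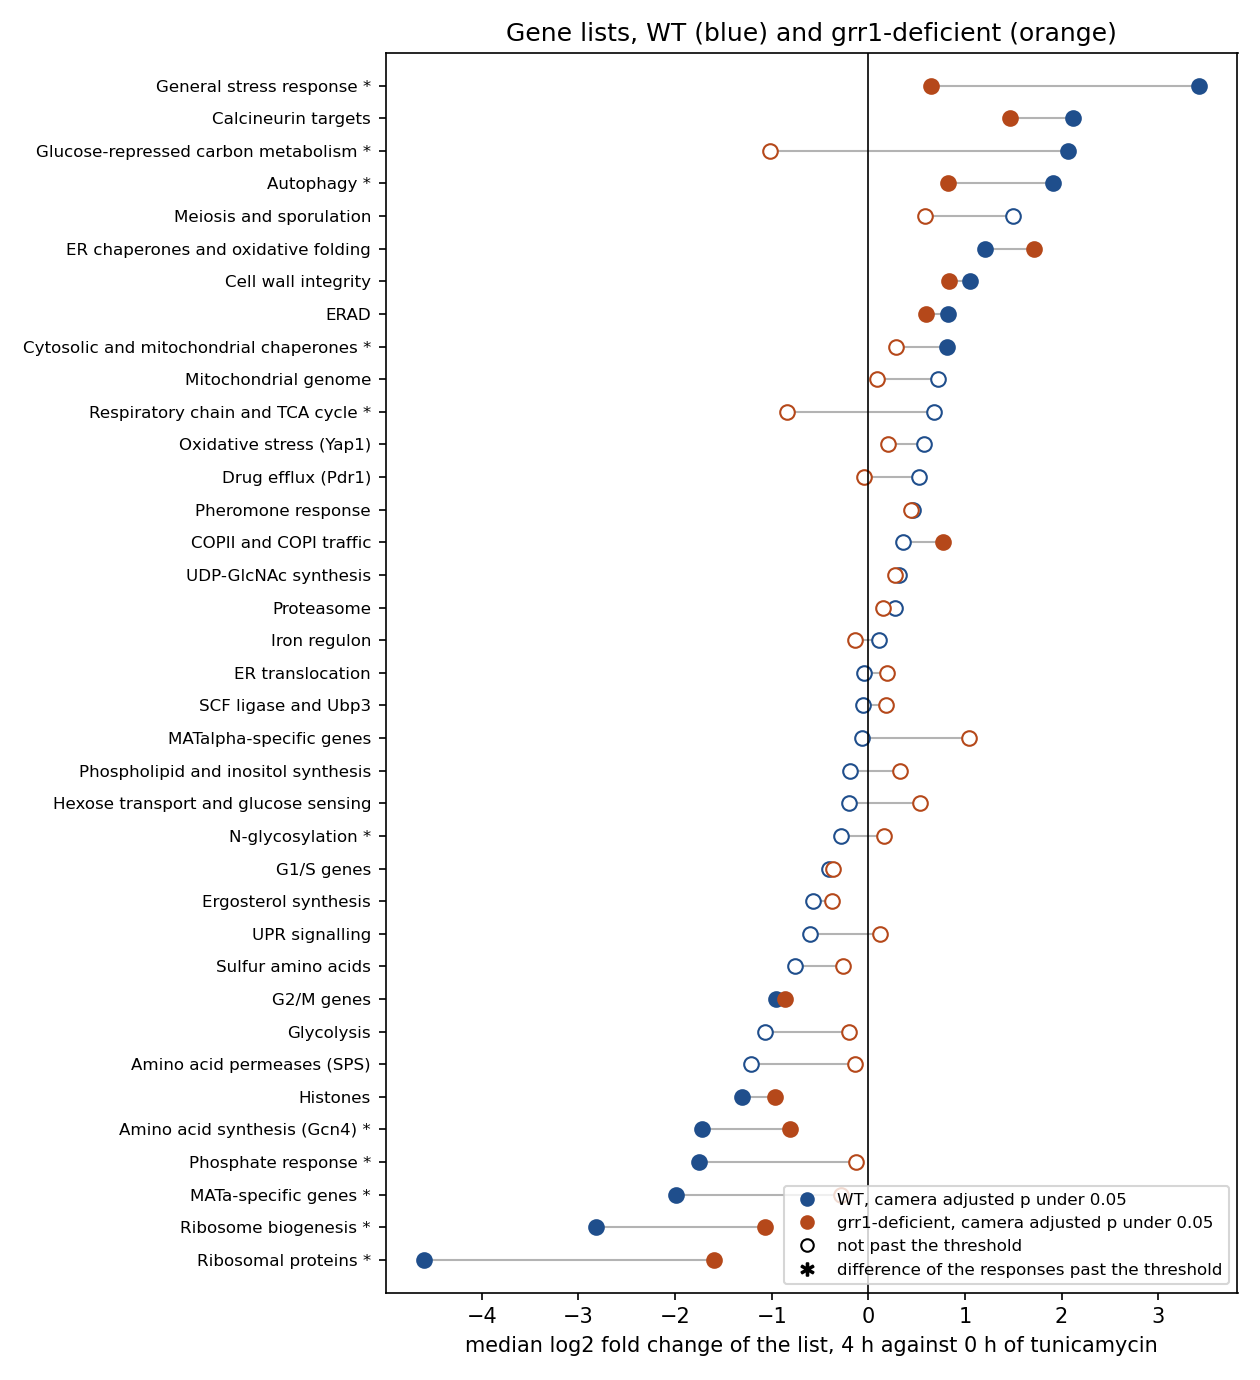
Median log2 fold change at 4 h against 0 h of tunicamycin for the members of 37 gene lists, in WT (blue) and grr1-deficient cells (orange). Filled points are lists past the camera test at an adjusted p of 0.05, and asterisks mark the 11 lists whose difference between genotypes passed.

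At 0 h, before tunicamycin, grr1-deficient cells had fewer transcripts of SPS amino acid permeases than WT, and more for general stress defence and for carbon sources other than glucose. As list calls these ended with an estimated correlation (adjusted p = 0.361, 0.395 and 0.361 in that order). GRR1 was 361.6-fold lower (154.8 to 1115, 95% counting interval), with a log2 change of −8.44 ± 0.25 (SE, edgeR adjusted p = 7.6e-07). The low-affinity glucose transporter gene HXT1 fell from 510.6 to 1.68 CPM (−8.32 ± 0.32, adjusted p = 2.8e-06), and the amino acid permease genes BAP3 and TAT1 fell by 8.02 ± 0.22 and 5.50 ± 0.23. MIG2, a repressor of glucose-repressed genes, was 66.0-fold lower (25.6 to 243), and PHO3 fell by 5.44 ± 0.28. TMA10 rose by 6.48 ± 0.30 and the cell wall gene PIR3 by 6.43 ± 0.60. HAC1 (0.09 ± 0.19, adjusted p = 0.722), KAR2 (−0.34, 0.155), ERO1 (−0.37, 0.221), IRE1 (0.02, 0.916) and UBP3 (−0.21 ± 0.19, 0.368) did not pass.

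In this comparison 2911 genes passed the edgeR test, 1316 higher and 1595 lower in grr1-deficient cells. Further large rises were those of JEN1, a lactate transporter gene (7.87 ± 1.77, adjusted p = 0.0223), and of CPP3 (6.47 ± 1.57), with RGI2 84.3-fold higher (32.5 to 312). JEN1 lay at 1468 CPM in grr1-deficient replicate 1 and at 94.3 CPM in replicate 2. YDL159C-B had 0 reads in WT at 0 h and was at least 5.67-fold higher, against 3 reads over the group. PDI1 (−0.75 ± 0.18, 0.00959) and BRE5 (−0.49 ± 0.14, 0.0201) were lower. Among hexose transport and sensing genes 6 were higher and 7 lower of 16 (camera adjusted p = 0.288), with HXT3 at −3.99 and STD1 at −3.07.

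Of 38 lists, 22 passed camera at 0 h, 8 higher and 14 lower. Glucose-repressed genes were higher, 16 of 23 with 1 lower (median 3.62, adjusted p = 8.6e-09), including FOX2 at 2.55 and CAT2 at 3.55, with medians of 3.96 in grr1-deficient replicate 1 and 2.34 in replicate 2, where mitochondrial transcripts were near 0. Cell wall integrity genes rose, 14 of 18 (1.08, adjusted p = 9.8e-05), with PTP2 at 1.44, and calcineurin targets rose, 6 of 9 (0.66, adjusted p = 0.0353), with YPS3 at 1.71. Ribosome biogenesis (49 of 50, −1.08, adjusted p = 3.4e-17) and ribosomal protein genes (129 of 135, −1.24, adjusted p = 2.0e-16) fell, with NSR1 at −1.61 and RPL6A at −1.46. SPS permeases fell, 9 lower and 1 higher of 11 (−2.44, adjusted p = 1.1e-05), with AGP1 at −4.62, and histone genes fell, 9 of 10 (−0.89, adjusted p = 0.00114), with HTB2 at −1.37. COPII and COPI traffic genes fell, 17 of 27 (−0.50, adjusted p = 0.00256, SEC31 at −1.05). ER translocation genes fell, 8 of 14 (−0.59, adjusted p = 0.00656, SSH1 at −1.08). Ergosterol synthesis (14 of 23, −0.53, ERG11 at −1.13) and MATa-specific genes fell (3 of 7, −0.89, STE2 at −1.94), adjusted p = 0.00424 each. The MATa median was −2.16 with replicate 1 and −0.79 with replicate 2. G1/S genes fell, 10 lower and 1 higher of 20 (−0.41, adjusted p = 0.0473, POL12 at −0.79). The SCF ligase list, which holds GRR1, fell with 5 of 10 lower (−0.30, adjusted p = 0.0445). With total counts the medians from COPII to SCF were −0.09, −0.18, −0.13, −0.42, −0.01 and 0.11. Each list from the glucose-repressed genes to the SCF ligase had an adjusted p = 0.361 with an estimated correlation.

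Phosphate response genes fell, 12 lower and 1 higher of 13 (median −2.30, camera adjusted p = 4.1e-09, and adjusted p = 0.181 with an estimated correlation), with PHO5 at −4.03 and PHO11 at −3.71. General stress genes rose, 19 of 25 (2.17, adjusted p = 3.2e-08, GAC1 at 4.71, HXK1 at 4.46). Medians were 1.63 and 2.66 with replicates 1 and 2. N-glycosylation genes fell, 17 of 28 (−0.48, adjusted p = 0.000959, median −0.08 with total counts, OST1 at −0.98). Both had an adjusted p = 0.395 with an estimated correlation. Autophagy genes rose, 12 higher and 1 lower of 22 (0.59, adjusted p = 0.00190, and adjusted p = 0.446 with an estimated correlation), with ATG39 at 4.22. Phospholipid synthesis genes fell, 10 lower and 1 higher of 15 (−0.51, adjusted p = 0.0300, and adjusted p = 0.453 with an estimated correlation), with EPT1 at −1.06. Respiratory and TCA genes rose, 10 of 37 (1.19, adjusted p = 0.000456, and adjusted p = 0.638 with an estimated correlation), with IDH1 at 2.16, though the median was 1.82 with replicate 1 and 0.14 with replicate 2. Sulfur amino acid genes rose, 8 higher and 4 lower of 22 (0.34, adjusted p = 0.0467, and adjusted p = 0.591 with an estimated correlation), with the sulfate permease gene SUL1 at 4.75. Meiosis genes rose, 4 of 14 (0.96, adjusted p = 0.0473, and adjusted p = 0.510 with an estimated correlation), with DIT1 at 2.16 and list medians of 0.33 with replicate 1 and 1.36 with replicate 2. Glycolysis (1 higher, 9 lower of 18, adjusted p = 0.251), iron (7 higher, 1 lower of 16, 0.0729), pheromone response (2 higher, 7 lower of 16, 0.0512) and ER chaperones (1 higher, 5 lower of 16, 0.251) did not pass.

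Adjusted over the list alone, counts at 0 h differed for glucose-repressed genes (17 higher, 1 lower), ribosome biogenesis (50 lower), ribosomal proteins (130 lower), COPII and COPI traffic (21 lower), ergosterol synthesis (15 lower), G1/S genes (1 higher, 11 lower), N-glycosylation (19 lower), the respiratory list (8 higher), meiosis (2 higher) and pheromone response (2 higher, 8 lower). For oxidative stress, UDP-GlcNAc synthesis and the mitochondrial genome the median, mean and test differed in sign. Total counts moved the median gene from −0.06 to 0.34 log2, gave 2106 genes higher and 646 lower, and ended the calls of PDI1 (−0.34, adjusted p = 0.173) and BRE5 (−0.08, 0.690). Against WT at 0 h, the mitochondrial genome median was 2.24 log2 with grr1-deficient replicate 1 and −9.59 with replicate 2. The list missed the threshold over all libraries (camera adjusted p = 0.816).

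Several list calls at 0 h rested on single libraries, on scaling or on the absence of a replicate block, which ended those of G1/S (adjusted p = 0.0541), meiosis (0.0516) and sulfur amino acid genes (0.0622). The SCF ligase call ended with total counts (adjusted p = 0.130), and without grr1-deficient 0 h replicate 1 (0.0545) or 4 h replicate 1 (0.0515). That of G1/S genes ended with total counts (0.150), and without WT 0 h replicate 2 (0.0909), grr1-deficient 0 h replicate 2 (0.111), and grr1-deficient 4 h replicates 1 (0.0515) and 2 (0.0581). Meiosis genes missed the threshold with total counts (0.192), and without WT 0 h replicate 2 (0.0710), grr1-deficient 0 h replicate 2 (0.290), and grr1-deficient 4 h replicates 1 (0.0622) and 2 (0.0733). Sulfur amino acid genes missed it with total counts (0.120), and without WT 0 h replicate 2 (0.111), grr1-deficient 0 h replicate 1 (0.0545), and grr1-deficient 4 h replicates 1 (0.0606) and 2 (0.0581). Calcineurin targets missed it without grr1-deficient 0 h replicates 1 (0.0535) and 2 (0.111), phospholipid synthesis without grr1-deficient 0 h replicate 2 (0.156), and the respiratory list without grr1-deficient 0 h replicate 1 (0.150) and with fry (0.134). Without both grr1-deficient replicate 2 libraries the calls of calcineurin targets (0.196), G1/S genes (0.192), meiosis (0.514), phospholipid synthesis (0.290) and sulfur amino acids (0.0895) ended. Over 12 alternatives, adjusted p ranged from 0.00178 to 0.130 for the SCF ligase, 0.00298 to 0.192 for G1/S genes, 0.0171 to 0.514 for meiosis genes, 0.0183 to 0.120 for sulfur amino acids, 0.00279 to 0.196 for calcineurin targets, 0.00851 to 0.290 for phospholipids and 2.6e-36 to 0.150 for the respiratory list, and was at most 0.0270 for the other 14 lists reported. With total counts, glycolysis (0.0418, within 0.00182 to 0.669), iron (0.0447, within 0.00740 to 0.357) and pheromone response (0.00941, within 0.00511 to 0.163) passed. Iron also passed without WT 0 h replicate 1 (0.0366) or grr1-deficient 0 h replicate 2 (0.00740), and pheromone response without WT 0 h replicate 1 (0.0131) or WT 4 h replicate 1 (0.0486) or 2 (0.0495). Without grr1-deficient 0 h replicate 2, hexose transport (0.0315, within 0.0160 to 0.528) and the proteasome (0.0446, within 0.0446 to 0.544) passed as lower.

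JEN1 lost its call at 0 h without WT 0 h replicates 1 (adjusted p = 0.113) and 2 (0.119) and without WT 4 h replicates 1 (0.0519) and 2 (0.0503), within 3.7e-21 to 0.142 over its alternatives. CPP3 lost it without those libraries (0.123, 0.126, 0.0584 and 0.0574) and without grr1-deficient 4 h replicates 1 (0.0563) and 2 (0.0579), within 4.3e-12 to 0.251. YDL159C-B lost it without WT 0 h replicates 1 (0.0970) and 2 (0.101) and grr1-deficient 0 h replicates 1 (0.0542) and 2 (0.118), within 0.00218 to 0.118. PDI1 lost it without WT 0 h replicate 2 (0.0852, within 0.000145 to 0.173), and BRE5 without WT 0 h replicate 2 (0.116) or grr1-deficient 0 h replicate 2 (0.0627, within 0.00131 to 0.690).

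At 4 h of tunicamycin, grr1-deficient cells had more transcripts of ribosome, sulfur and Gcn4-regulated amino acid genes than WT, and fewer of proteasome genes and of cytosolic and mitochondrial chaperones. No list call held at 4 h with an estimated correlation (adjusted p = 0.566 or more for each list). GRR1 was lower (log2 −7.60 ± 0.21 SE, edgeR adjusted p = 9.1e-07), as were HXT1 (−7.85 ± 0.30), BAP3 (−6.72 ± 0.20), MIG2 (−4.53 ± 0.43), HXT3 (−4.40 ± 0.27) and the serine and threonine deaminase gene CHA1 (−4.04 ± 0.21). SUL1 was higher by 4.98 ± 0.37 (24.2 against 764 CPM), MAL12, a maltase gene, by 3.96 ± 0.70, PIR3 by 3.86 ± 0.49 and YIG1 by 4.35 ± 0.80. From low counts in WT, YDL159C-B was 36.4-fold higher (15.3 to 113, 95% counting interval) and FRE5 22.3-fold (9.99 to 62.0). KAR2 (0.03 ± 0.18, adjusted p = 0.904), ERO1 (−0.45, 0.172), PDI1 (0.48, 0.0783), HAC1 (0.06 ± 0.19, 0.845), UBP3 (0.43 ± 0.18, 0.108) and BRE5 (0.18, 0.366) did not pass. IRE1 (0.59 ± 0.14, 0.0153) and LHS1 (1.48 ± 0.14, 0.000322) were higher.

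Here 1836 genes passed the edgeR test, 1008 higher and 828 lower, and 12 of 38 lists passed camera, 5 higher and 7 lower. Sulfur amino acid genes were higher, 12 of 22 with 1 lower (median 0.77, adjusted p = 1.3e-07), with MET1 at 2.09 ± 0.12 and MMP1 at 2.85 ± 0.21. Ribosomal protein genes were higher, 133 of 135 (1.79, adjusted p = 2.7e-43), with RPS14B at 2.12, and held 4.69% and 4.89% of gene reads in the grr1-deficient libraries at 4 h. Cell wall integrity genes were higher, 9 of 18 (0.41, adjusted p = 0.00169), with PIR1 at 2.86 and HSP150 at 1.61. SPS permeases were lower, 7 of 11 with 1 higher (−1.15, adjusted p = 2.7e-06), with TAT1 at −3.83 and medians of −1.68 with replicate 1 and −0.76 with replicate 2, and cytosolic and mitochondrial chaperones, 11 of 22 (−0.55, adjusted p = 0.00285), with HSP42 at −1.23. G1/S genes were lower, 8 of 20 with 2 higher (−0.28, adjusted p = 0.0120), among them the G1 cyclin genes CLN1 (−1.10) and CLN2 (−1.04), and histone genes, 6 of 10 (−0.47, adjusted p = 0.0133), with HTA1 at −0.83. Each list from the sulfur amino acids to the histones had an adjusted p = 0.566 with an estimated correlation.

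Ribosome biogenesis genes were higher at 4 h, 35 of 50 (median 0.68, camera adjusted p = 9.7e-10), with NOP58 at 1.42, and Gcn4-regulated genes, 22 of 31 with 1 lower (0.87, adjusted p = 1.5e-05), with GCN4 itself at 1.85. Proteasome genes were lower, 21 of 32 with 1 higher (−0.44, adjusted p = 0.000128), with RPN6 at −0.75, and autophagy genes, 8 of 22 (−0.43, adjusted p = 0.00481), with ATG7 at −0.98 and medians of −0.28 with replicate 1 and −0.52 with replicate 2. These 4 lists had an adjusted p = 0.585 with an estimated correlation. General stress genes were lower, 7 of 25 with 1 higher (−0.70, adjusted p = 0.00285, and adjusted p = 0.608 with an estimated correlation), with GAD1 at −2.09 and GAC1, which was higher, at 2.24. Hexose transport and sensing genes had 2 higher and 5 lower of 16 (0.23, adjusted p = 0.0525). Adjusted over the list alone, counts differed for ribosome biogenesis (38 higher), Gcn4 (24 higher, 2 lower), proteasome (1 higher, 24 lower), chaperones (13 lower), G1/S (2 higher, 9 lower) and hexose transport (4 higher, 7 lower). The median, mean and test differed in sign for hexose transport, G2/M, the mitochondrial genome, N-glycosylation, meiosis, pheromone response, ER chaperones and UDP-GlcNAc synthesis, none of which passed.

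Total counts moved the median gene from −0.003 to −0.28 log2 at 4 h, gave 562 genes higher and 1620 lower, and ended the calls of IRE1 (adjusted p = 0.147) and of general stress (0.0565). The number of called genes was 588 without WT 4 h replicate 1, 553 without WT 4 h replicate 2 and 1127 without grr1-deficient 4 h replicate 2, and 2742 genes and 16 lists passed without both grr1-deficient replicate 2 libraries. Autophagy missed the threshold without grr1-deficient 4 h replicate 2 (0.0988, the highest over its 12 alternatives) or both grr1-deficient replicate 2 libraries (0.0825). General stress missed it without grr1-deficient 4 h replicate 1 (0.161, its highest) and with fry (0.155), against 0.0482 at most for the other 10 lists. Glucose-repressed genes (0.115) passed as higher with total counts (0.0176) and without grr1-deficient 0 h replicate 1 (0.0178) or 2 (0.0165), within 1.1e-07 to 0.161. Hexose transport (0.0525) passed with a replicate block (0.0372), and without WT 4 h replicate 1 (0.0193) or 2 (0.00686) or grr1-deficient 4 h replicate 2 (0.00571), within 0.00571 to 0.196. The SCF ligase list (0.0639) passed as lower without WT 4 h replicate 1 (0.0289) or 2 (0.0456) or grr1-deficient 4 h replicate 2 (0.00142), within 0.00142 to 0.129. Oxidative stress genes (0.0597) did so without WT 4 h replicate 1 (0.0369) or grr1-deficient 0 h replicate 1 (0.0178) or 2 (0.0165), within 0.00706 to 0.152. Without grr1-deficient 4 h replicate 1, ergosterol synthesis (0.0419, and 0.0493 without WT 4 h replicate 2, within 0.0258 to 0.160), the respiratory list (0.0419, within 0.0419 to 0.909) and the mitochondrial genome (0.0262) passed as lower. Against WT at 4 h, the mitochondrial genome median was instead 1.47 log2 with grr1-deficient replicate 1, and −13.71 with replicate 2. Glucose-repressed medians were 0.55 and 0.515, those of oxidative stress −0.45 and −0.36, and those of the SCF ligase list −0.12 and −0.07. That list holds GRR1, so a lower result is in part built into the strain, and it was not tested without GRR1. Leaving out WT 4 h replicate 1 or 2 ended the calls of IRE1 (0.0955 and 0.122, within 0.00108 to 0.147) and MAL12 (0.0789 and 0.0972, within 4.0e-15 to 0.0972), and the YIG1 call ended without them too (0.0612 and 0.0815) and without grr1-deficient 4 h replicate 2 (0.0534, within 4.6e-09 to 0.0815).

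Across 5855 genes, the WT and grr1-deficient responses to tunicamycin had a Pearson correlation of 0.697 (Spearman 0.71), and genes are not independent replicates. The correlation was 0.447 without grr1-deficient 4 h replicate 1 and 0.506 without grr1-deficient 0 h replicate 1. A total least squares line of the grr1-deficient on the WT response had a slope of 0.446. Of 2207 genes called in both responses, 984 rose in both, 1134 fell in both and 89 went opposite ways, where independent lists would share 409.6 rises and 475.2 falls. Among genes called in WT, the median absolute log2 change was 1.17 in WT and 0.59 in grr1-deficient cells. The correlation was 0.742 over replicate 1 libraries and 0.564 over replicate 2 libraries.

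The authors' deposited table for WT calls 4240 of 5734 genes, 2089 higher and 2151 lower, and 3751 of these were also called here. Among shared genes, 489 were called by the authors alone and 14 here alone. Their deposited table for grr1-deficient cells calls 1813 of 5719, 758 higher and 1055 lower, and 1795 of these were called here. In this genotype 18 were called by the authors alone and 872 here alone. The fit of all 8 libraries shares its spread between the genotypes. With only the 4 libraries of each comparison, 4659 genes passed the edgeR test in WT and 1642 in grr1-deficient cells. The sign was equal for 99.4% of 5702 and 99.7% of 5704 shared genes. In the authors' deposited tables KAR2 changes by 2.16 in WT and 2.55 in grr1-deficient cells, and PDI1 by 1.23 and 2.46. HAC1 changes by 0.14 (authors' adjusted p = 0.266) and 0.12 (0.768) in the same deposited tables.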

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

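The test of library scaling was chosen only after the result was seen. Results in this part are those where the responses to tunicamycin of WT and grr1-deficient cells differed by the edgeR interaction test or, for lists, by camera at a preset correlation, and read classes outside the comparisons that exceeded their WT 0 h level.

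Glucose-repressed, general stress, respiratory and autophagy genes and cytosolic and mitochondrial chaperones had lower responses in grr1-deficient cells. Median differences (log2, grr1-deficient minus WT response) were −3.01, −2.83, −1.45, −1.05 and −0.68 in that order. The first 4 were already above WT at 0 h (medians 3.62, 2.17, 1.19 and 0.59), against 0.46, −0.70, −0.26 and −0.43 at 4 h. With an estimated correlation the camera adjusted p = 0.381, 0.514, 0.747, 0.514 and 0.403 in that order, and the respiratory call also ended with fry (0.195, its highest) and without grr1-deficient 0 h replicate 1 (0.0565). Single genes with lower responses were HSP12 (−6.95), TMA10 (−6.65), POT1 (−5.63), HSP26 (−5.23), ARO10 (−5.01), YMR206W (−4.98), ATG39 (−4.28), PGM2 (−4.18), GLK1 (−3.50), CAT2 (−3.09), HSP42 (−2.97), HSP78 (−2.37), IDH1 (−2.18), LSC2 (−1.80), FOX2 (−1.68), ATG19 (−1.42) and ALG13 (−1.35). The HSP12 and HSP26 calls ended without any single library other than the grr1-deficient ones at 0 h, up to an edgeR adjusted p of 0.0800 and 0.147.

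Ribosome, phosphate response, MATa-specific and Gcn4-regulated genes had higher responses in grr1-deficient cells. Median differences were 3.02 (ribosomal proteins), 2.17 (MATa), 1.77 (ribosome biogenesis), 1.66 (phosphate), 1.10 (Gcn4) and 0.48 (N-glycosylation, −0.21 with total counts). Medians against WT were −1.24, −0.89, −1.08, −2.30, −0.33 and −0.48 at 0 h and 1.79, 0.52, 0.68, −0.29, 0.87 and 0.001 at 4 h. With an estimated correlation the camera adjusted p = 0.381 for the first 3, 0.227 for phosphate and 0.708 for Gcn4 and N-glycosylation. The N-glycosylation call also ended in 7 of 12 alternatives (0.00830 to 0.262 over all), among them fits without 1 library. The Gcn4 call ended with fry (0.0538, its highest). Higher-responding genes were PHO3 (5.38), PHO5 (4.38), HMS2 (4.36), YJR146W (4.22), RPL9A (4.11), HXT4 (3.99), RPL6A (3.88) and PHO11 (3.84). Others were STE2 (3.14), DBP2 (3.13), RPS22B (3.07), LEU9 (2.94), STE6 (2.17), SSF1 (2.13) and CPA1 (1.51). In the ER and Ubp3 lists they were LHS1 (1.24), PDI1 (1.23), OST1 (1.12), EUG1 (0.84), EPS1 (0.75) and BRE5 (0.67). Of these LHS1 alone kept its call with total counts. BRE5 lost its edgeR call without WT 4 h replicate 1 (adjusted p = 0.0879) or 2 (0.115), WT 0 h replicate 2 (0.112), and grr1-deficient 0 h replicate 2 (0.0592) or 4 h replicate 2 (0.0568), within 0.00932 to 0.943 over its alternatives. EUG1 lost it without any 1 WT library, within 6.4e-06 to 0.739, and PDI1 without WT 4 h replicate 2, within 1.4e-05 to 0.127.

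Ribosomal protein transcripts fell further in WT than in grr1-deficient cells, by a median of 3.02 log2 over 135 genes. The tables argue against library scaling as the whole cause, since the list median was 3.017 with TMM, 3.03 with DESeq2 size factors and 2.336 with total counts, which moved the median of all genes from 0.03 to −0.65, and the lower quartile of the list stayed at 1.957 or more. They also argue against reads shared between paralogs, since the 18 single-copy genes had a median difference of 3.093 against 2.993 for the 117 paired ones. Time in culture rather than tunicamycin cannot be told apart, since 0 untreated libraries taken at 4 h entered the comparison. A lower level in grr1-deficient cells at 0 h (median −1.24) does not cover the whole difference, since 133 of 135 genes were higher there at 4 h (median 1.79), and a difference between the genotypes in the response stays open, untested, as a hypothesis.

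The share of counted reads outside genes was at most 5.60% in the WT libraries at 0 h. It was 7.99% and 7.73% in WT at 4 h, 6.73% and 11.6% in grr1-deficient cells at 0 h, and 10.1% and 21.7% in grr1-deficient cells at 4 h, in replicate order.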

How the results depend on the processing

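Leaving out both replicate 2 libraries of the grr1-deficient strain, leaving out mitochondrial-genome genes, coding-region reads, voom with library weights and DESeq2 beside the authors' tables were alternatives chosen only after the data were seen. Of 16559 values of 839 named results under the alternatives, 15682 kept their side of the threshold without a called reversal, though 119 of these changed sign while not called, 698 lost a call, 169 gained one and 10 reversed. A reversal is a change of sign with a call in the main fit or in the alternative, and none of the 10 was called in both. Of 732 calls, 200 were lost under at least 1 alternative, 151 of them without a single library and 93 with total counts.

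A 2-fold threshold left 2247 genes in WT, 1107 in grr1-deficient cells, 1384 for the interaction, 1260 at 0 h and 604 at 4 h, as a stricter test must. With only the 4 libraries of the comparison, 4659 genes passed in WT and 1642 in grr1-deficient cells, and voom with library weights gave 4563 and 1927. Leaving out each library in turn gave 3087 to 4061 genes in WT, 2267 to 2724 in grr1-deficient cells, 1272 to 2470 for the interaction, 1953 to 3123 at 0 h and 553 to 2263 at 4 h. The interaction fell to 1365 without WT 0 h replicate 2, 1397 without WT 4 h replicate 1 and 1272 without WT 4 h replicate 2. At 4 h the count was 588 and 553 without WT 4 h replicates 1 and 2 and 1127 without grr1-deficient 4 h replicate 2. A group left with a single library was assumed to vary like the others. Without both replicate 2 libraries of the grr1-deficient strain, the 5 counts in the order above were 4694, 3388, 2857, 3556 and 2742. That last fit takes its spread from WT alone, where replicates differed by an SD of 0.278 and 0.204 log2 at 0 h and 4 h. In grr1-deficient cells the SD was 0.586 and 0.484. Its higher counts therefore do not show more change, and the causes of the other shifts were not tested.

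With an estimated correlation, camera passed 0 lists in WT, 0 in grr1-deficient cells, 0 for the interaction, 0 at 0 h and 0 at 4 h. At an unadjusted p under 0.05 it gave 5, 3, 4, 2 and 3 lists, and the smallest adjusted p were 0.296, 0.184, 0.227, 0.181 and 0.566. Fry, which tests the direction of a list without comparing it with other genes, passed 30, 17, 19, 27 and 19 lists. Without a single library, 5, 6, 2, 4 and 7 reported lists that had missed the threshold passed in at least 1 fit. The replicate numbers are shared between groups, but nothing in the labels says that a number marks a shared culture or day. With the replicate number as a block, 4096, 3042, 2560, 2922 and 1899 genes and 18, 14, 12, 19 and 13 lists passed. Deviations from the group means correlated between 0 h and 4 h at 0.796 in grr1-deficient cells (0.46 over nuclear genes) and 0 in WT (0.003), a hint of pairing in the former from 2 libraries per group.

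The correlation of the 2 responses, 0.697 with all libraries, lay between 0.447 and 0.697 with each library left out, at 0.506 without grr1-deficient 0 h replicate 1 and 0.447 without grr1-deficient 4 h replicate 1. Leaving out either of these leaves the grr1-deficient replicates unpaired between 0 h and 4 h. Total counts reversed BRE5 (−0.022), POL12 (−0.067) and SEC63 (−0.06) in the interaction, CDC4 (0.047) and QRI1 (0.076) at 0 h, and IRE1 (0.30), RUB1 (0.24), YEA4 (0.34) and UBP3 (0.56, adjusted p = 0.0115) in WT. That scaling moved the median gene from 0.03 to 0.78 in WT, so weak changes moved with it. ERO1 reversed to 0.49 in the interaction without both replicate 2 libraries of the grr1-deficient strain, and the cause was not tested. Depth limits genes near the floor of 3 reads, such as GRR1 in grr1-deficient cells.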

Other observations

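The tests of RNA loss in preparation and of a mislabelled strain were chosen only after the results were seen.

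Members of lists that passed in neither response to tunicamycin also changed in edgeR. The hexose transporter gene HXT5, which is induced when growth slows, rose by 4.99 ± 0.29 log2 in WT and by 1.59 ± 0.25 in grr1-deficient cells, with a difference of −3.40 ± 0.36 (edgeR adjusted p = 0.000351). PDC1, the main pyruvate decarboxylase gene of glycolytic fermentation, fell by 2.32 ± 0.20 in WT, was at 0.08 ± 0.19 in grr1-deficient cells (edgeR adjusted p = 0.767) and differed by 2.39 ± 0.27. FAR1, which arrests the cell cycle in response to pheromone, fell by 3.85 ± 0.14 in WT and 1.57 ± 0.14 in grr1-deficient cells, and the response of the G1 cyclin gene CLN3 was higher in grr1-deficient cells by 2.64 ± 0.41. The ferroxidase gene FET3 fell by 3.94 ± 0.23 and 2.11 ± 0.22, while TIS11, which destabilises mRNAs under low iron, rose by 3.46 ± 0.31 in WT, with a difference of −2.31 ± 0.41 in grr1-deficient cells. Of oxidative stress genes, OYE3 rose by 3.80 ± 0.30 in WT and was already higher by 2.54 ± 0.30 at 0 h in grr1-deficient cells. GFA1, which makes glucosamine 6-phosphate for UDP-GlcNAc, the donor used at the step tunicamycin blocks, rose by 1.97 ± 0.28 in WT and was higher by 1.76 ± 0.28 at 0 h in grr1-deficient cells.

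Reads in 89 Ty retrotransposon genes, whose copies are too alike to separate, made up 2.21% and 3.74% of gene reads in WT at 0 h and 6.12% and 6.58% at 4 h. In grr1-deficient cells they made up 3.84% and 5.37% at 0 h, and 8.58% and 24.4% at 4 h, in replicate order. These shares were looked up after the data were seen, and replicate 2 of the grr1-deficient strain held the highest at each time.

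The grr1-deficient libraries at 0 h lay toward the WT state at 4 h of tunicamycin. Both comparisons rest on the same WT 0 h libraries, yet the covariance of their log2 changes was 0.959, against a mean of 0.078 and a highest of 0.151 in 100 simulations of unchanged groups, while the correlation of 0.618 lay below the highest simulated one of 0.647 (mean 0.498). The covariance was 0.829 with grr1-deficient replicate 1 alone and 1.02 with replicate 2 alone (correlations 0.554 and 0.571), and 0.785 (correlation 0.592) after leaving out 210 genes of the ribosome and general stress lists, which argues against shared controls, a single replicate or those lists as the whole cause. Genes called higher in both numbered 787 and lower in both 1224, against 428.2 and 527.4 for independent lists, with 259 opposite. Part of that excess may come from the shared controls, since the comparison was not run with a separate WT 0 h library for each side. The difference in genotype stays among the open explanations, and its causes were not tested.

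Transcripts of the mitochondrial genome were near 0 in replicate 2 of the grr1-deficient strain, except for Q0092, which was 219.1-fold and 241.8-fold higher there than in replicate 1 at 0 h and 4 h. A general loss of mitochondrial RNA in library preparation would lower every mitochondrial transcript, so the smaller ratio of 219.1 argues against it, and GRR1 at 0.9455 CPM or less in both libraries argues against a strain with GRR1. Loss of most mitochondrial DNA with a retained, amplified piece is a candidate explanation, and it predicted higher nuclear retrograde-response genes in replicate 2. Their median over 8 genes was instead lower, at −0.39 and −0.20 log2 against −0.13 and 0.01 for random lists, which met the bound set beforehand for ruling it out, at percentiles of 1.73 and 7.75 among 10000 lists, so beyond their spread at 0 h but not at 4 h. That the spread must be exceeded at both times was required only after the result was seen, and since Grr1 is known to target Mks1, a repressor of these genes, the test is weak in cells without Grr1 and the explanation stays open.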
